A study of Mus musculus with 2 samples.

How the data were processed

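Chromatin from mouse liver was immunoprecipitated with an antibody against SMRT, a corepressor that nuclear receptors recruit to DNA, and the recovered DNA was sequenced. Per the labels' protocols and the series' design text, livers of 12-week-old male C57BL/6 mice fed without restriction were taken at Zeitgeber time (ZT) 10 and at ZT22, with 4 mice per time. Each animal was immunoprecipitated on its own and the material of a time was then pooled into 1 library, so there were 2 libraries and no biological replicates. Per the labels' protocols, libraries were amplified for 15 PCR cycles and fragments of about 250 bp were selected.

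Each library came with 1 list of peaks. HOMER and the genome build mm8 are named in the submitters' processing notes. The aligner, the peak-calling settings, any input control and the number of sequenced reads are not given in the sources used here, so the depth behind each peak is unknown. The authors gave each peak a score, deposited with 1 decimal and sorted from high to low, and its scale is not given in the sources used here. The lowest deposited score was 1.0 in both lists, and every peak was 200 bp wide. Since its scale is unknown, the score was used mainly to rank and filter peaks within a list. The planned ratio of tag counts at shared peaks was not computed. Where peaks of both lists are counted at the same score, equal scores may not stand for equal signal.

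The group of each list was taken from the labels of its sample. The peak names inside each list carry the opposite clock time: those of the sample labelled ZT10 (5 pm) read 5 am, and those of the sample labelled ZT22 (5 am) read 5 pm. The files do not settle which is right, so the libraries are called by their sample labels and any statement of direction swaps if the peak names are right.

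Peaks of the lists were called overlapping when they shared at least 1 bp. The count was checked with bedtools 2.31.1, which gave the same numbers. Chance overlap was measured by placing each list's peaks at random 1000 times between the first and last listed peak of their chromosome, and, as an alternative chosen after seeing the data, by shifting all peaks by 10 kb in either direction. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and not the spread between mice. With 1 library per time, no p-value was computed for a difference between times. Ties in the score were broken at random with a fixed seed where a list was split by rank. Runs of neighbouring peaks were joined where starts lay up to 5 kb apart. For runs, and for the distance of single peaks to shared ones, chance rested on 100 random placements. Peaks were counted in windows of 1 Mb, and the allotment of single-library peaks to windows was simulated 1000 times with no regional difference. The overlap count was tested on simulated lists of 21370 peaks, where a true share of 59.9% was recovered as 60.1%. The simulated shared peaks were copies moved too little to lose their overlap, so this checked the counting only. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6 were used.

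The peaks to be named were fixed before the data were examined: the 10 strongest of each list and the 5 strongest of each list without overlap in the other. The runs, windows, chromosome X and the remaining peaks with a score of 5 or more were chosen after their values were seen. Gene names, gene lists, locations relative to genes and sequence motifs, which were planned, were not analysed here, because the lists name no genes and the gene table at hand is of build GRCm38. Peaks of the ZT10 list reached past the last gene of that table on 7 chromosomes. Of its peaks, 10.2% lay within 1 kb of a gene end there as given, against 10.1% and 10.0% after shifts of 10 kb up and down, so that table was not used for position. For the ZT22 list these shares were 10.3%, 9.84% and 10.1%. All coordinates are 1-based and in mm8, the build in the submitters' processing notes.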

Results

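Occupancy of the corepressor SMRT was mapped in mouse liver by chromatin immunoprecipitation and sequencing. SMRT is tethered to DNA by nuclear receptors such as those for thyroid hormone and retinoic acid, and it brings histone deacetylase activity with it. Livers were compared at ZT10, late in the light phase, and at ZT22, late in the dark phase, to ask how its occupancy differs between these times. Each time was represented by 1 library pooled from 4 male C57BL/6 mice, so the values below have no replicate check. The list labelled ZT10 held 21370 peaks and the list labelled ZT22 held 24078, covering 4.27 and 4.82 Mb. Read depth is unknown. The peak names within each list carry the clock time of the other sample, so each direction below rests on the sample labels and swaps if the peak names are right.

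Most SMRT peaks of each library were also called in the other. Of the peaks in the ZT10 library, 14597 (68.3%, 95% interval 67.7 to 68.9) overlapped a peak of the ZT22 library. In the other direction, 14595 ZT22 peaks (60.6%, 60.0 to 61.2) overlapped a ZT10 peak. Peaks placed at random on the same chromosomes overlapped the other list at 0.412% and 0.365%, and shifting all peaks by 10 kb gave 1.74% and 1.54%. Merging the lists gave 30845 regions. Of these, 14590 (47.3%) held peaks of both times, 6772 (22.0%) of ZT10 alone and 9483 (30.7%) of ZT22 alone. Overlapping peaks were closely aligned, with a median of 19 bp between their centres. Absence from a list is not absence of binding, since both lists end at a score of 1.0. Nor does a peak in both lists by itself show SMRT binding, since any input control is unknown.

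Most of the strongest sites were shared between the times. Of the 10 strongest peaks, 9 of the ZT10 list and 9 of the ZT22 list overlapped the other list. The strongest ZT10 peak, on chromosome 19 at 5803589 to 5803788 (score 14.8), ranked 8 in the ZT22 list. The strongest ZT22 peak, on chromosome 2 at 25294715 to 25294914 (score 14.4), ranked 2 in the ZT10 list. A site on chromosome 7 at 6014183 to 6014382 was called at the identical position in both libraries and ranked 5 at ZT10 and 2 at ZT22. Sites on chromosome 5 at 140456607 to 140456806 and on chromosome 18 at 75725190 to 75725389 ranked 3 and 7 at ZT10 and lay 3 and 1 bp from the peaks ranked 4 and 3 at ZT22. The ZT10 peaks on chromosome 11 at 58118631 to 58118830 and at 115846612 to 115846811 and on chromosome 6 at 136432587 to 136432786 ranked 9, 8 and 10, and their ZT22 partners ranked 6, 23 and 11. The site on chromosome 9 at 44632355 to 44632554 ranked 6 at ZT10 and 57 at ZT22. Ranks 7, 9 and 10 of the ZT22 list fell to shared sites on chromosome 19 at 4989079 to 4989278, chromosome 14 at 62635700 to 62635899 and chromosome 4 at 137591688 to 137591887. Of the 1000 strongest peaks of each list, 761 overlapped one another. Of the 1000 strongest ZT10 peaks, 973 overlapped some ZT22 peak, as did 987 of the 1000 strongest ZT22 peaks in the ZT10 list.

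Weak peaks had a listed partner less often than strong ones. Each list was divided by score into 4 parts of equal size. Of the ZT10 peaks, 94.9% (94.2 to 95.4) overlapped in the strongest part, followed by 82.3% and 59.7%, and 36.4% (35.1 to 37.7) in the weakest. The ZT22 list ran from 88.2% (87.4 to 89.0) through 68.4% and 51.8% to 34.0% (32.8 to 35.2). The intervals of neighbouring parts did not overlap in either list. Peaks without a partner had a median score of 1.3 at ZT10 and 1.4 at ZT22, against 2.0 and 1.9 for overlapping peaks, and 90.1% and 86.1% of them scored below 2.

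**Figure D1:**
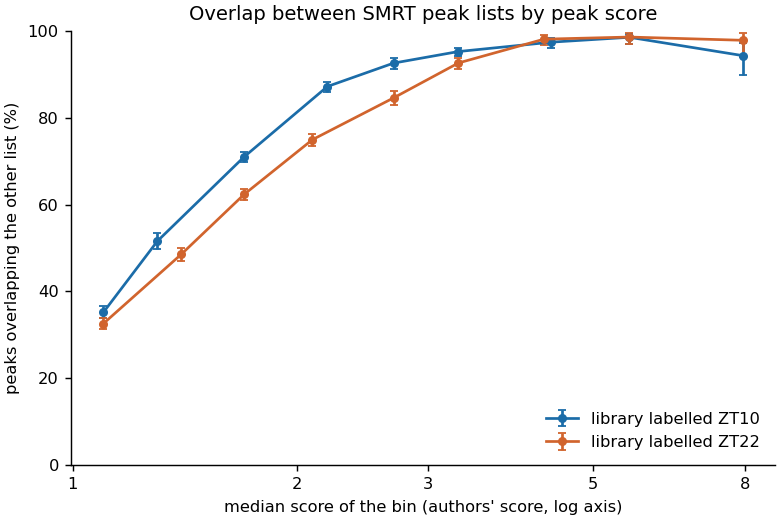
Share of peaks that overlap the other list (vertical axis, percent) against the median score of each score bin (horizontal log axis, the authors' score), for the libraries labelled ZT10 and ZT22; bars are exact 95% intervals that cover counting error only. Overlap climbs from 35.2% and 32.6% in the lowest bin to 98.6% and 98.7% for scores from 5 to below 7, and is 94.4% (89.9 to 97.3) and 97.9% (94.0 to 99.6) at scores of 7 or more.

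The surplus of ZT22 peaks lay at scores below 3. The ZT22 list held 2708 more peaks than the ZT10 list, 1.13 times as many. At scores below 2 it held 15772 peaks against 13043, whereas 8306 ZT22 and 8327 ZT10 peaks had a score of 2 or more. The ZT22 list was still ahead at scores from 2 to below 2.5, with 3497 against 3248 peaks. From 2.5 to below 3 it held 1932 against 1783. At scores of 3 or more the order turned, with 2877 ZT22 and 3296 ZT10 peaks. The near tie at 2 or more thus joins opposite differences. Whether a score stands for the same signal in both libraries is not given in the sources used here.

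A few strong sites had no overlapping partner. In the ZT10 list these were 17 peaks with a score of 5 or more, of which 6 lay within 1 kb of a ZT22 peak, and 6 lay more than 10 kb from any. The strongest, on chromosome 11 at 108827964 to 108828163, ranked 4 with a score of 13.7 and had no ZT22 peak closer than 55.9 kb. On chromosome 8, a peak at 112879547 to 112879746 (score 10.1) stood beside others at 112879845 to 112880044 (8.1) and 112880153 to 112880352 (8.3), with the nearest ZT22 peak 6.25 kb away. The remaining 3 of the 5 strongest were close neighbours of ZT22 peaks: those on chromosome 12 at 104740166 to 104740365 and at 104739569 to 104739768 lay 332 and 265 bp from one, and that on chromosome 9 at 45980062 to 45980261 lay 296 bp from one. In the ZT22 list 9 such peaks were found, of which 5 lay within 1 kb of a ZT10 peak and 1 lay beyond 10 kb. The strongest, on chromosome 12 at 104739834 to 104740033 (score 11.8), fell between the 2 ZT10 peaks just named, and the next, on chromosome 4 at 49570229 to 49570428 (7.9), lay 704 bp from a ZT10 peak. The other 3 of the 5 strongest were on chromosome 1 at 90044873 to 90045072 (7.2, 6.75 kb away), chromosome 5 at 146565411 to 146565610 (6.7, 12.4 kb) and chromosome 6 at 47707769 to 47707968 (6.7, 3.39 kb). More of these strong single peaks were of ZT10, but the order turned at a lower cut. At scores of 5 or more, 97.5% of ZT10 and 98.5% of ZT22 peaks overlapped the other list. At scores of 2 or more these shares were 92.0% and 84.2%. No library had a replicate, and counting error was not measured for single peaks.

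**Figure D2:**
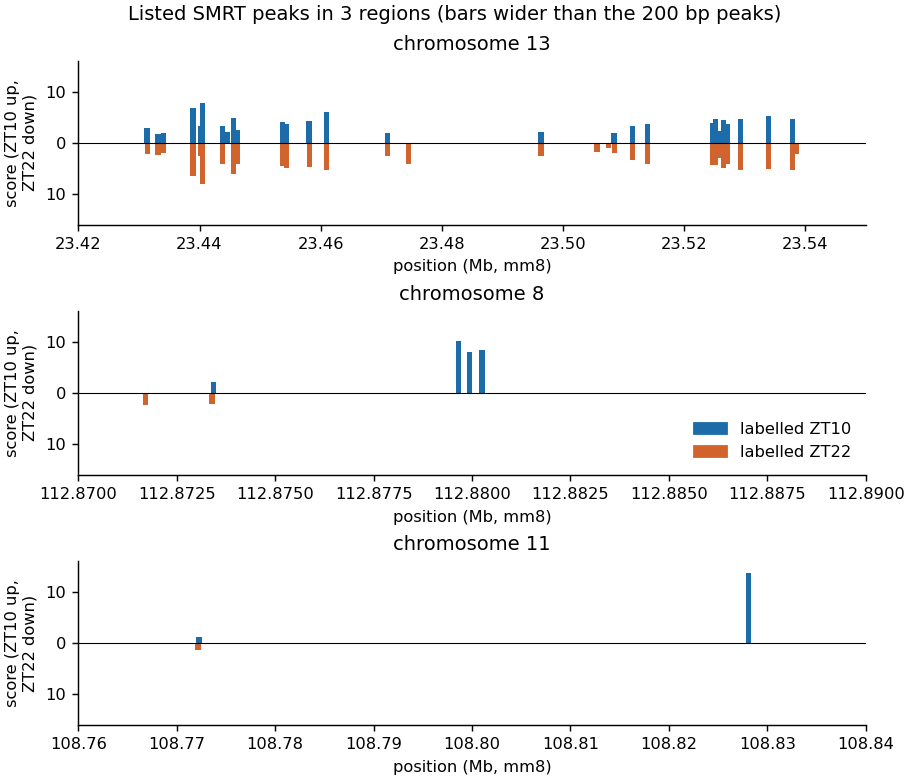
Listed peaks in 3 regions by position (horizontal axis, Mb in mm8) with the authors' score on the vertical axis, upward for the library labelled ZT10 and downward for that labelled ZT22; each bar is 1 peak and is drawn wider than its 200 bp. The runs on chromosome 13 are present in both lists, whereas the chromosome 8 group of 3 peaks and the chromosome 11 peak with a score of 13.7 appear at ZT10 alone.

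Peaks were grouped along the genome, and the fullest groups were present in both lists. Runs of peaks up to 5 kb apart took in 42.2% of ZT10 and 44.4% of ZT22 peaks, against 8.70% and 9.84% for 100 random placements. These placements were uniform along each chromosome, so any uneven spread of peaks would exceed them. A run may also be 1 broad region listed as several 200 bp peaks, which was not examined. The ZT10 run with most peaks was on chromosome 13 at 23431243 to 23446322, with 10 ZT10 and 9 ZT22 peaks. A neighbouring ZT10 run at 23524583 to 23537961 held 8 peaks. The ZT22 run there, at 23524582 to 23538675, held 9, as many as the ZT22 run at the first site. Runs of 8 peaks were also found on chromosome 9 at 42011645 to 42030911 at ZT10, where ZT22 had 5, and on chromosome 4 at 131335042 to 131351929 and chromosome 17 at 8110602 to 8122873 at ZT22, where ZT10 had 5 and 7. Across 2034 windows of 1 Mb, peak numbers of the libraries correlated with a Pearson r of 0.96 and a Spearman rho of 0.95; this is across windows, which are not replicates. The windows with most peaks over both lists were chromosome 10 from 79000001 to 80000000, with 71 ZT10 and 76 ZT22 peaks, and chromosome 2 from 167000001 to 168000000, with 73 and 74.

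Chromosomes 11 and 19 carried the most peaks per Mb, and chromosome X the fewest. All mice were male, and peak numbers were not adjusted for chromosome copy number. Density was 14.2 peaks per Mb at ZT10 and 15.8 at ZT22 on chromosome 11, 12.6 and 14.9 on chromosome 19, and 0.947 and 0.736 on chromosome X. Each of the 19 autosomes had more ZT22 than ZT10 peaks, by 1.09 to 1.18 times. Chromosome X went the other way, with 153 ZT10 and 119 ZT22 peaks, or 0.716% (0.607 to 0.838) and 0.494% (0.410 to 0.591) of the lists. Of the peaks on X without a partner, 70 were of ZT10 and 36 of ZT22, so ZT10 made up 66.0% (56.2 to 75.0), against 38.5% to 44.2% on the autosomes. The strongest X site, at 97425273 to 97425472 in the ZT10 list, was shared and scored 10.0 at ZT10 and 9.4 at ZT22. X peaks were weak, with median scores of 1.3 and 1.4.

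**Figure D3:**
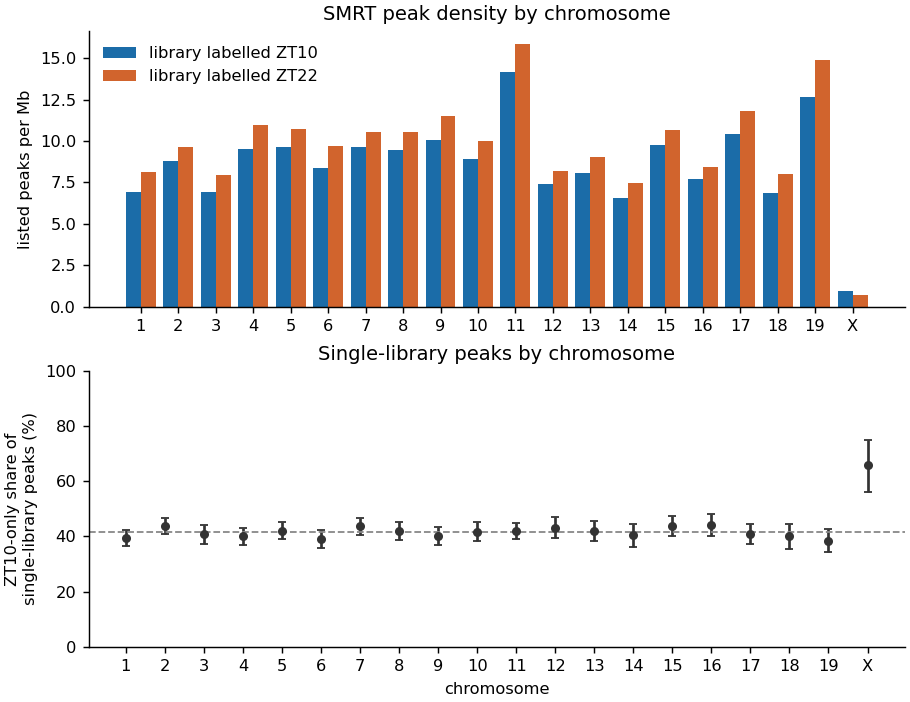
Upper panel: listed peaks per Mb between the first and last listed peak of each chromosome, for the libraries labelled ZT10 and ZT22. Lower panel: the share of peaks without a partner that came from ZT10 (percent, exact 95% intervals for counting error only), with the genome-wide 41.7% as a dashed line; chromosome X, at 66.0%, lies above all 19 autosomes.

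No 1 Mb window stood apart from chance in the balance of single-library peaks. The most uneven toward ZT22 was chromosome 4 from 100000001 to 101000000, with 0 ZT10-only and 13 ZT22-only peaks; 205 of 1000 simulations with no regional difference held a window as uneven. Next came chromosome 6 from 108000001 to 109000000, with 4 and 25, matched in 215 of 1000. The most uneven toward ZT10 was chromosome 9 from 56000001 to 57000000, with 8 and 0, matched in 308 of 1000.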

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

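The overlap shares depended on the definition more than on counting error, and overlap was higher in the strongest than in the weakest of the 4 parts under the 1 bp, 50% reciprocal, 100 bp and 1000 bp definitions. Requiring 50% reciprocal overlap gave 65.5% of ZT10 and 58.1% of ZT22 peaks; centres within 100 bp gave identical values, since all peaks are 200 bp wide. Centres within 1000 bp gave 75.0% and 66.8%. Under 50% reciprocal overlap the strongest of the 4 parts of each list gave 92.5% at ZT10 and 86.0% at ZT22 and the weakest 34.4% and 31.8%; within 1000 bp these were 97.0%, 90.7%, 46.7% and 42.5%. Keeping the upper 50% of each list by score gave 75.0% and 66.6%. The same number of strongest peaks from both lists, 25% of the shorter list, gave 72.0% in either direction. Scores of 2 or more in both lists, chosen after seeing the data, gave 71.3% and 71.5%. Overlap is nearly one to one, so the shares in the 2 directions differ almost entirely through list length, and lists of near equal length give near equal shares. The ratio of ZT22 to ZT10 peak numbers was 0.997 at scores of 2 or more and 0.873 at 3 or more, on the other side of 1 from the 1.13 of the full lists. Restriction to autosomes and X removed no peak and so tested nothing. The alternatives for strong single peaks, X and runs were likewise chosen after seeing the data. Strong single peaks, 17 at ZT10 and 9 at ZT22, numbered 24 and 14 under 50% reciprocal overlap and 11 and 4 within 1000 bp. The ZT10-only share on X lay between 65.5% and 73.9% over its alternatives, though it rested on 23 peaks in the upper 50%, 13 at scores of 2 or more and 3 among the equal numbers of strongest peaks. Peaks in runs changed from 42.2% to 27.0% at ZT10 and from 44.4% to 27.5% at ZT22 with neighbours up to 2 kb apart, and to 56.5% and 59.2% with 10 kb. No paired analysis was possible because each time has 1 pooled library, and no library could be left out for the same reason. The alternatives planned for tag count ratios, genes, gene lists, locations and motifs were not run, as these results were not analysed here. Unknown read depth limits what a missing weak peak can show.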

Other observations

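Of the tests in this part, those of the 3 X windows and of neighbouring peaks had their outcomes stated before the values were seen; the others were chosen after. Within 10 kb of a shared peak of the same list lay 41.8% of single ZT10 and 41.4% of single ZT22 peaks, against 9.10% and 9.15% for 100 random placements. Peaks of a list cluster in general: with the shared and single labels shuffled 100 times among its listed peaks, 45.3% (44.1 to 46.5 over the shuffles) and 44.5% (43.4 to 45.7) lay as near, so single peaks lay near shared ones slightly less often than such random picks. The hypothesis that single-library peaks of one time gather in particular 1 Mb windows was tested in the 660 windows with 10 or more such peaks. It was not borne out there. The standard deviation of the balance, in units of its chance spread, was 1.02, and simulations with no regional difference reached 1.09. Sparser windows were left out. Chromosome X had 106 single-library peaks over 50 windows, so most of its windows fell below this limit. On a finer scale, neighbouring single-library peaks 1 to 10 kb apart came from the same library in 54.2% of 3163 pairs, against a mean of 51.4% and a highest value of 54.0% in 1000 shuffles of the library labels. The shuffles used only which list a peak was in, not its score. Whether this small excess reflects local domains that differ between the libraries was not tested. Time of day and a difference between the pooled samples cannot be told apart here.

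Whether the surplus of ZT22 peaks, 24078 against 21370, comes from calls near the listing limit could not be decided from the scores. The ratio of ZT22 to ZT10 peaks was 1.105 (1.06 to 1.15) at scores from 1.0 to 1.2 and 1.53 (1.46 to 1.60) at 1.3 and 1.4, with 2630 against 1395 peaks at 1.4 alone. In wider bins it was 1.27 (1.23 to 1.30) below 1.5 and 1.13 (1.08 to 1.17) from 1.5 to below 2. The narrow and wide bins thus disagree, and rounding to 1 decimal fills bins unevenly. The ZT22 count at 1.4 stood above both neighbouring scores, with 1889 peaks at 1.3 and 1509 at 1.5. The ZT10 count fell steadily, with 1560 at 1.3 and 1263 at 1.5. The ratio of 1.53 thus leans on the score of 1.4. The wide bin below 1.5 also holds the peaks at 1.4, so its higher ratio is no separate evidence of a rise toward the limit. At the lowest score, 1.0, the lists were nearly equal, with 1090 ZT22 and 1088 ZT10 peaks. A deeper ZT22 library also remains open. The ZT22 scores pile up as whole multiples of a step of 0.0467 would (deviance 695 for a smooth curve, 165 with the step), as read counts divided by a constant could; for ZT10 the best step, 0.0509, improved the fit less (282 to 185). The ratio of the steps, 1.09, would be the ratio of depths only if both were right and scores were read counts divided by depth. The scale of the score is not given, and the ZT10 step is too poorly determined to tell. The time of day itself was not tested apart from these, since each time has 1 library.

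Chromosome X held fewer peaks at ZT22, opposite to each autosome. Weak calls were not in general short at ZT22: on the autosomes it had 1.21 times as many peaks with scores below 2 (15673 against 12915). That ratio restates the surplus of weak ZT22 peaks described above and is no separate test. A few windows do not account for the balance on X. Without the 3 X windows with most ZT10-only peaks, which held 15 of them, ZT10 still made up 62.5% (51.5 to 72.6) of the single peaks. On the autosomes its share was 41.5%, below that interval. At scores of 2 or more, X held 25 ZT10 and 20 ZT22 peaks, too few to compare. A difference between the pooled animals or libraries and a difference by time of day both stay open and were not tested.

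Of the 17 strong ZT10 peaks without overlap, 11 had no ZT22 peak within 1 kb, so a ZT22 call of the same site shifted by up to 1 kb cannot account for all 17. It stays open for the 6 that had one. The chromosome 8 group made up 3 of the 11. Whether such sites lie in repeated sequence was not analysed here, and no biological explanation was tested.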
